A study of Homo sapiens with 3 samples.

How the data were processed

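Nuclear RNA of Raji cells was measured on 3 NimbleGen tiling arrays, 1 for each of 3 biological replicates that form a single group. Raji is a B cell line derived from a Burkitt lymphoma. Per the labels, the cells were arrested with 1.5% DMSO for 96 h and taken 6 h after release, in early G1 phase. The RNA was copied into double-stranded cDNA, sheared to about 250 bp, labelled with Cy5 and hybridized together with sheared Raji genomic DNA carrying Cy3. The dyes were not swapped. Because both cDNA strands were labelled, the signals carry no strand information.

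Per the file headers, NimbleScan 2.4.27 extracted the 635 nm image (Cy5, RNA) and the 532 nm image (Cy3, genomic DNA). The deposited scanner tables hold a linear intensity for each spot, with no background subtraction or scaling between arrays visible in the values. The deposited ratio tables hold the log2 of Cy5 over Cy3 minus the array's Tukey biweight mean. This was checked against the scanner tables and held within 0.005 on all 3 arrays. Coordinates are those of the array design, counted from 1, and the genome build is not given in the sources used here. The annotation at hand was for GRCh38, so no probe was placed on a gene, exon or intron. That annotation served only to name the genes beside MYC.

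The array held 389307 spots. Of these, 384662 were tiling probes of 50 bp. The 44 regions of the ENCODE pilot project held 382884 of them, with starts a median of 38 bp apart. A separate chromosome 8 tile that the design files label as c-MYC held 1778 probes at a median spacing of 50 bp. Another 1111 probes carried random sequence, and 1767 probes for 31 control sequences were spotted in duplicate. Random and control probes were kept out of the tiling analysis.

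For each tiling probe, the log2 ratio of Cy5 to Cy3 was taken from the scanner signals as given and centred on the array's median over tiling probes. No loess or quantile step was used. Since RNA was set against genomic DNA, the trend of ratio with brightness was taken to be part of the signal. This was not tested, and without a dye swap a dye effect that changes with brightness cannot be told apart from it. A value of 0 is therefore the median tiling probe and not a level without RNA. Probes were averaged in windows of 1000 bp with at least 5 probes, which gave 22460 windows with a median of 17 probes, and over each of the 45 tiled regions. Windows and regions were tested against 0 with limma 3.58.1 (lmFit with an intercept, then eBayes) in R 4.3.3, with the data.table package, version 1.17.8. Benjamini-Hochberg adjusted p-values under 0.05 were called, over windows and over regions separately. All tests were 2-sided. In 22460 simulated windows, the window test recovered 54% of 50 windows raised by 1 on the log2 scale and 96% of 50 raised by 2. It recovered 6% of 50 raised by 0.5 and 4% of 50 set at -0.5, with 0 false calls. All other simulated windows were set at 0, with noise drawn independently for each window. In the data far more windows were called, and whole arrays differed in range. These rates, the false calls among them, therefore do not carry over to the data. The number of arrays limits the precision.

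Randomly picked ENCODE pilot regions have names of the form ENr followed by 3 digits, whose second digit is the stratum of gene density (1 low, 2 middle, 3 high). This comes from the naming scheme of the pilot project and not from the files. The genes given for ENm regions come from general knowledge of the project and not from the files either. The 10 regions per stratum were compared by permutation tests with 100000 resamples (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). Figures were drawn with matplotlib 3.10.9.

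Named windows are the 10 with the highest and the 4 with the lowest mean among called windows, at least 10000 bp apart, and named regions are the 5 highest and the 5 lowest. This rule, the tests and most alternatives were chosen before the data were examined. The log2 threshold of 1, the joining of windows into runs and the splitting of the MYC tile were chosen after the data were seen. A run is a series of measured windows, all called with a log2 ratio of at least 1, with gaps of at most 5 unmeasured windows. Other regions, windows and runs named in the text were also chosen after their values were seen.

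The alternatives chosen beforehand were normexp background correction (offset 50) with loess, the deposited ratios as they are and centred on their median, quantile normalization, centring on the mode, medians of probes, and windows of 500 and 5000 bp. Probes in the lowest 10% of Cy3 signal were left out, each replicate was left out in turn, and limma's treat tested against a log2 ratio of 0.5. Alternatives chosen after seeing the data were the Cy5 channel alone, centring on the random probes, leaving out the MYC tile, and the share of windows at a log2 ratio of 1 or more as the measure for the gene density strata. Planned comparisons of genes, exons with introns, annotation classes and gene lists, and the correction for probe GC content, were not run for want of an annotation and a genome of the files' build. With 1 group, no comparison between groups was made.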

Results

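The series measured nuclear RNA of Raji cells, a B cell line from a Burkitt lymphoma, in early G1 phase. Such lymphomas carry a translocation that joins MYC, a transcription factor gene that drives cell growth, to an immunoglobulin locus. The array tiled 44 ENCODE pilot regions and a stretch of chromosome 8 around MYC. The 3 biological replicates form 1 group, each on its own array, and genomic DNA of the same cells served as the reference on every array. The question was which parts of the tiled genome gave RNA signal above the rest. All ratios are log2 of RNA over genomic DNA relative to the array's median probe, as mean ± SD over n = 3 arrays, and every adjusted p comes from limma. Coordinates are those of the array design, whose genome build is not given in the sources used here, so no signal is assigned to a gene.

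Window ratios were correlated between replicates. Pearson's r between arrays across windows was 0.927 for replicates 1 and 2, 0.920 for 1 and 3, and 0.948 for 2 and 3. Across single probes it was 0.763, 0.714 and 0.761 for the same pairs. Windows and probes are not independent replicates, so these are descriptions. Replicate 3 gave a narrower range, with an SD across windows of 0.491 against 0.688 and 0.679 for replicates 1 and 2. It was the lowest of the 3 arrays in 1645 of the 1680 windows called with a log2 ratio of at least 1.

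Most probes lay close to background in the RNA channel. The median Cy5 signal of tiling probes was 508, 603 and 491 on arrays 1 to 3, and that of random-sequence probes was 440, 534 and 448. The share of tiling probes above the random probes' 95th percentile was 20.5%, 18.1% and 14.9% for Cy5 and 28.1%, 21.0% and 17.9% for Cy3. Random probes had a median log2 ratio 0.16 ± 0.05 above that of tiling probes. Signals include this background, so folds are ratios of raw brightness, and they are lower bounds where RNA probes were saturated.

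High ratios of RNA to DNA were concentrated in a small part of the tiled sequence. Of 22460 windows, 4808 were higher than the array median, with a median log2 ratio of 0.75, and 1680 of them (7.48%) reached 1 or more. Their median RNA signal lay 2.26 above the array median on the log2 scale and their median DNA signal 0.65 above it. Of the 45 regions, the 6 with the most held 818 (48.7%) of these 1680 windows, while 9 regions held none. Those 6 differ in size: in ENm004 the share was 126 of 1219 windows (10.3%), in the MYC tile 106 of 147 (72.1%). Another 4140 windows were lower than the array median, by little: their median was -0.34, and 3507 of them lay between -0.5 and 0. The count of lower windows fell to 1897 without replicate 1 and to 1421 without replicate 2, was 1255 with centring on the mode and 99 under treat against 0.5, and was 11854 with centring on the random probes.

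The window with the highest measured ratio lay on chromosome 6 in region ENr223, from 74225000 to 74225999. Its log2 ratio was 5.32 ± 0.06, at least 39.9-fold over the median probe (adjusted p = 3.9e-07). In Cy5, 11 of its 26 probes were saturated on at least 1 array, which also narrows the SD. Of the other 9 named high windows, those with saturated Cy5 probes are given as "at least". The order of the named high windows is thus that of measured values and is not settled. ENm007 is the region of the leukocyte receptor complex, whose genes encode immune cell receptors. Such genes name a whole region here, and no window was placed on a gene. The region held 2 of the 10 named high windows, which lie at least 10000 bp apart. The one at 59397000 on chromosome 19 had a log2 ratio of 4.61 ± 0.42 (at least 24.4-fold, adjusted p = 1.0e-05), and the one at 59661000 had 4.44 ± 0.48 (at least 21.7-fold). In ENm002, the interleukin gene cluster region of chromosome 5, the window at 131898000 reached 4.51 ± 0.69 (at least 22.7-fold, adjusted p = 3.1e-05). In ENm006, on the distal long arm of the X chromosome, the window at 152095000 reached 4.52 ± 0.48 (at least 22.9-fold). The named window of the MYC tile, at 128707000 on chromosome 8, reached 4.38 ± 0.51 (at least 20.9-fold, adjusted p = 2.0e-05). ENr333 on chromosome 20 reached at least 4.25 ± 0.27 at 34958000, and ENr122 on chromosome 18 reached at least 4.10 ± 0.24 at 59788000, where 6 probes were measured.

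A pair of the named high windows lay in regions with few others. In ENm009, the region of the beta-globin genes, which are expressed in red cell precursors, the window at 5695000 on chromosome 11 had a log2 ratio of 4.25 ± 0.58 (adjusted p = 2.6e-05). Whether this window lies on one of those genes was not determined. The mean of that region was -0.13 ± 0.02, and 19 of its 736 windows reached 1. In ENr322 the window at 97429000 on chromosome 14 had a log2 ratio of 4.62 ± 0.27 (at least 24.6-fold, adjusted p = 3.0e-06). It was the single window of 396 in that region to reach 1. The mean of ENr322 was -0.09 ± 0.12 and did not pass, while with the RNA channel alone it was 0.51 ± 0.20 and was called higher (adjusted p = 0.0068). It was called lower with normexp and loess (-0.39 ± 0.13, adjusted p = 0.0052) and with quantile normalization (-0.08, adjusted p = 0.041).

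The MYC tile had the highest ratio of RNA to DNA of the 45 tiled regions. Its mean log2 ratio was 1.84 ± 0.29 (3.59-fold, adjusted p = 4.4e-05), with 2.06, 1.96 and 1.51 on arrays 1 to 3. Of its 147 windows, 106 (72.1%) were called at 1 or more. The tile held 0.655% of all windows tested but 6.31% of those at 1 or more.

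Bright signal filled the measured windows at both ends of the MYC tile and was missing from those in a stretch between them. The lengths given include sequence without a window of at least 5 probes. From 128605000 to 128710999, a length of 106 kb, 84 of 84 windows were higher, 75 of them at 1 or more. Their mean was 2.39 ± 0.37 (5.26-fold). From 128711000 to 128762999, a length of 52 kb, 0 of 31 windows were higher, 9 were lower and the mean was -0.19 ± 0.04. From 128763000 to 128802999, a length of 40 kb, 32 of 32 windows were higher, 31 of them at 1 or more. Their mean was 2.01 ± 0.37 (4.02-fold). Genomic DNA signal differed little between these parts, at 0.33 ± 0.07, 0.22 ± 0.09 and 0.43 ± 0.11 on the log2 scale, while RNA signal was 2.70 ± 0.32, 0.01 ± 0.10 and 2.41 ± 0.27. In the GRCh38 annotation MYC lies between the noncoding RNA genes CASC11 and PVT1. Whether each of these genes lies in a bright stretch, in the middle one or outside the tile was not determined. In the middle stretch, 8 windows were higher with the RNA channel alone and 1 with normexp and loess. Its 9 lower windows numbered 5 without replicate 2, 3 with centring on the mode, 0 under treat, and 23 with centring on the random probes. Under the alternatives, 75 to 84 windows were higher in the first bright stretch, with 75 under treat and 78 without replicate 2. In the last stretch 29 to 32 were higher, where 29 were measured with dim DNA probes left out.

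**Figure D1:**
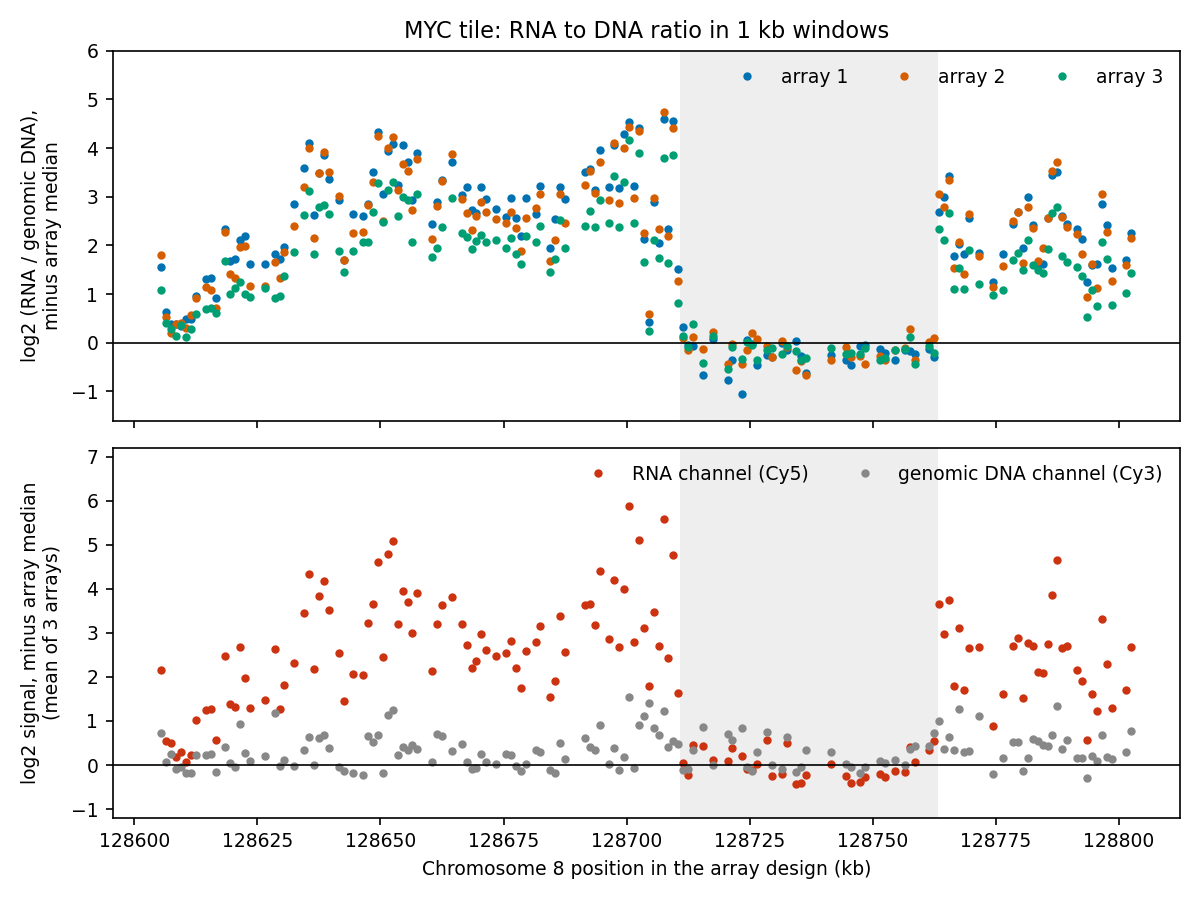
RNA signal along the MYC tile in windows of 1000 bp, by chromosome 8 position in the array design (kb). The upper panel gives the log2 ratio of RNA to genomic DNA on each of 3 arrays, the lower panel the mean log2 signal of each channel, both relative to the array median; the shaded stretch of 52 kb, where 0 of 31 windows were higher, separates bright stretches of 106 and 40 kb.

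After the MYC tile, the regions with the highest ratios were ENr333 on chromosome 20 (0.93 ± 0.17, adjusted p = 0.00013), ENm008 on chromosome 16 (0.80 ± 0.21, adjusted p = 0.00031), ENr231 on chromosome 1 (0.72 ± 0.14, adjusted p = 0.00017) and ENm006 on X (0.67 ± 0.16, adjusted p = 0.00031). ENm008 is the region of the alpha-globin genes, and 129 of its 387 windows reached 1 (33.3%). The share was 40.7% in ENr333, 29.4% in ENr231 and 23.6% in ENm006. The lowest region means were those of ENm012 (-0.20 ± 0.05), ENr312 (-0.20 ± 0.08), ENm010 (-0.19 ± 0.09), ENr311 (-0.19 ± 0.03) and ENr213 (-0.18 ± 0.04), with adjusted p from 0.0069 to 0.011. ENm012, the region of FOXP2, a transcription factor gene of brain development, had 2 higher and 236 lower windows of 818, and 0 reached 1. ENm010, the region of the HOXA genes, which pattern the embryo, had 13 higher and 129 lower windows of 398, and 4 reached 1. With the RNA channel alone, ENm010 lay at 0.23 and ENr312 at 0.15, above the array median, and the order at the top changed: ENm008 (1.75) and ENr332 (1.57) came before ENr333 (1.55). With normexp and loess, ENr324 (0.70) came before ENm008 (0.55) and ENm006 (0.51).

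In all, 20 regions were higher, 16 were lower and 9 did not pass. These are means of probes set against the array's median probe, so bright probes in part of a region can raise it. With medians of probes, 17 of the 20 higher and 16 of the 16 lower regions were still called. ENm005 (0.02, adjusted p = 0.65), ENr121 (0.08, adjusted p = 0.093) and ENm004 (0.05, adjusted p = 0.19) no longer passed as higher. The lower regions spanned means of -0.20 to -0.13, and their count was 4 without replicate 2 and 0 with centring on the mode. Under treat against 0.5, 4 of the 20 higher and 0 of the 16 lower regions were still called. ENm006 was not among these (adjusted p = 0.16 from treat). With normexp and loess, 14 of the 20 higher regions were still called and 3 had means below 0 that were not called, among them ENm007 at -0.09 (0.28 ± 0.14 as reported here). Of the 16 lower regions, 9 were still called with it and 4 had means above 0, and ENm012, at -0.08, no longer passed (adjusted p = 0.075). Centred on the random probes, 8 of the 20 were still called.

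**Figure D2:**
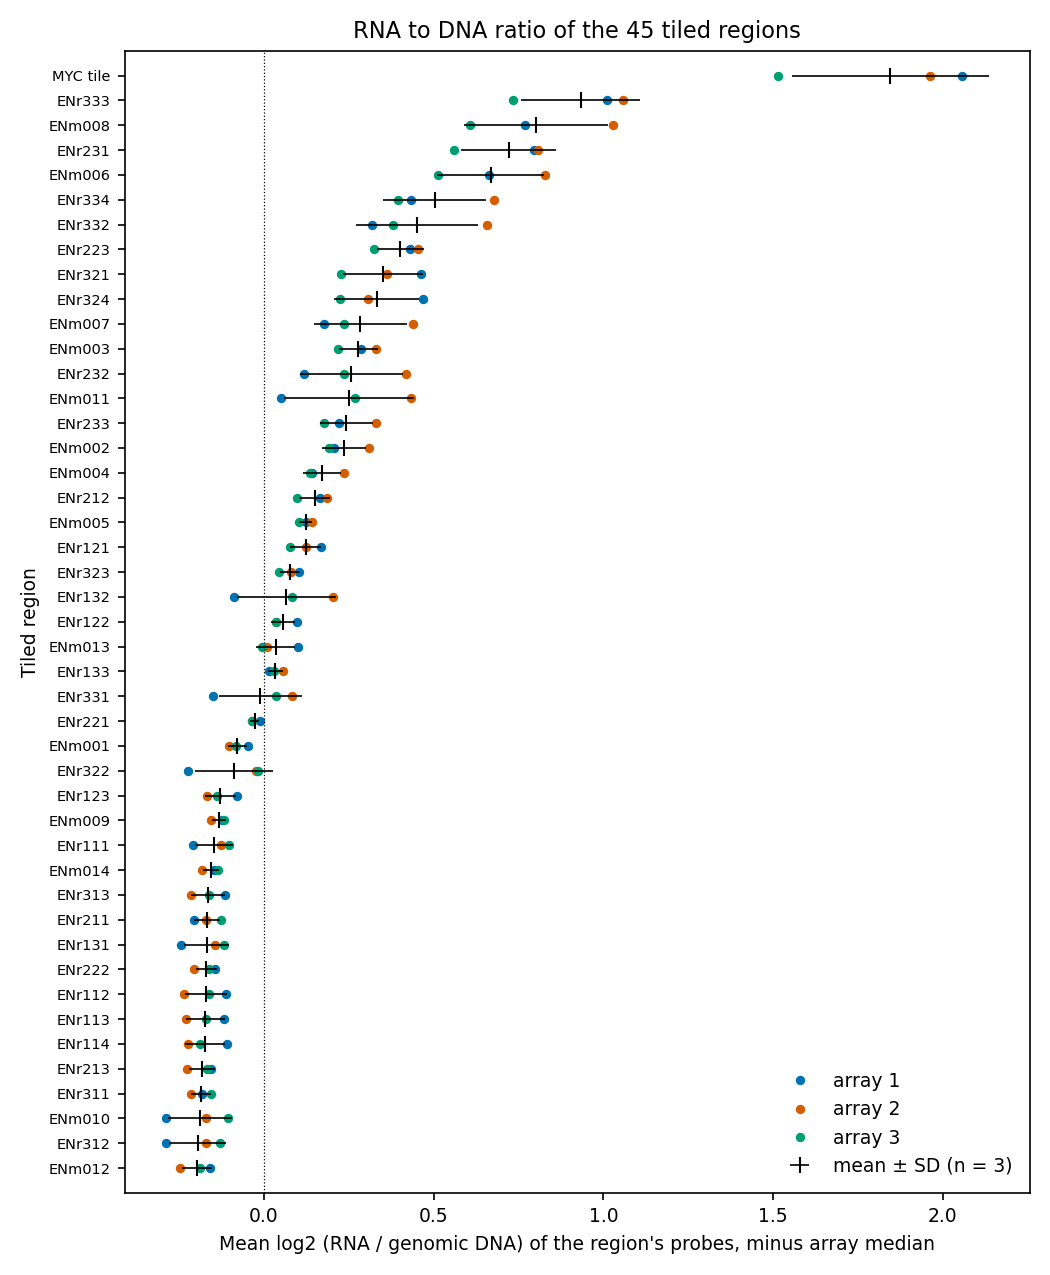
Mean log2 ratio of RNA to genomic DNA over the probes of each of the 45 tiled regions, relative to the array median. Points are the 3 arrays, and bars give the mean ± SD; the MYC tile lies at 1.84 and the next region, ENr333, at 0.93.

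Bright windows often lay in long runs. The 1680 windows formed 542 runs, of which 286 were a single window. Another 37 runs were 10 kb or longer, lay in 16 regions and held 638 (38.0%) of the windows. The longest, of 86 kb, lay in the MYC tile from 128618000 to 128703999 with a mean log2 ratio of 2.68 ± 0.40. The next, of 52 kb, lay in ENr334 on chromosome 6 from 41698000 to 41749999, at 2.10 ± 0.47. In ENm002 a run of 33 kb began at 131856000 (1.66 ± 0.37), and in ENm004 on chromosome 22 a run of 32 kb began at 30337000 (1.83 ± 0.45). ENm006 held a run of 25 kb from 151681000 (2.34 ± 0.54) and one of 24 kb from 152044000 (2.97 ± 0.62). In the beta-globin region ENm009, a run of 22 kb from 5675000 to 5696999 had a mean of 2.58 ± 0.42 and held 17 of the region's 19 windows at 1 or more.

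Ratios of RNA to DNA were higher in randomly picked regions of higher gene density. The mean log2 ratio was -0.14 ± 0.10 (SD, n = 10 regions) in the low stratum, 0.09 ± 0.21 in the middle one and 0.30 ± 0.35 in the high one. High minus low was 0.44 (2-sided permutation p = 0.00038), and it was 0.38, 0.58 and 0.38 on arrays 1 to 3. Spearman's rho with the stratum over the 30 regions was 0.679 (permutation p = 5e-05). The share of windows called at 1 or more was 0.232% ± 0.454, 5.09% ± 6.16 and 13.6% ± 13.6 in the low, middle and high strata. That share differed by 13.4 percentage points between high and low (permutation p = 0.0002). With normexp and loess, the difference in mean ratio was 0.18 (permutation p = 0.24) and rho was 0.198 (permutation p = 0.30), while the share of windows at 1 or more still differed by 12.2 points (permutation p = 0.0019). Genomic DNA signal, summarized by stratum for array 1 alone, also rose with the stratum, from 0.01 to 0.12 and 0.67 on the log2 scale. Probe GC content was not corrected for, so an effect of probe brightness was not separated from gene density. The first digit of the region names was not taken into account in these tests. In the high stratum, regions with a first digit of 1 had means of -0.17 to 0.07. Those with 2 had 0.24 to 0.72, and those with 3 had -0.01 to 0.93.

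**Figure D3:**
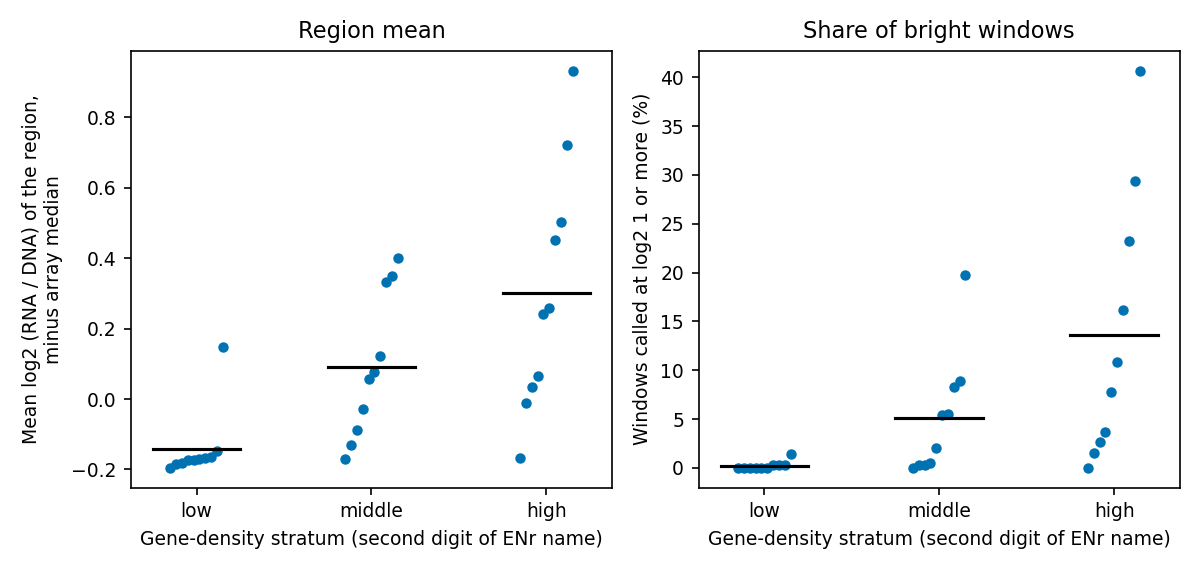
RNA signal of the 30 randomly picked regions by gene density stratum, 10 per stratum. The left panel gives the region's mean log2 ratio relative to the array median, the right panel the percent of its windows called at a log2 ratio of 1 or more; bars mark stratum means, which rise from -0.14 to 0.30 and from 0.232% to 13.6%.

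Windows far below the array median were few and were bright in genomic DNA. Only 74 of the 22460 windows had a called log2 ratio of -1 or less. In 73 of the 74 the DNA signal lay at least 1 above the array median on the log2 scale, and in 71 the RNA signal was at or above the array median. That median itself lay close to the random probes, so a ratio this low is hardly reached without bright DNA. In ENm007 the window at 59119000 on chromosome 19 had a ratio of -3.65 ± 0.42 with DNA 4.91 ± 0.36 and RNA 1.24 ± 0.11 above the median (adjusted p = 2.3e-05). In Cy3, 7 of its 27 probes were saturated, so its DNA signal is a lower bound and its ratio an upper one. Neighbouring windows with 9 and 11 saturated probes lay at -3.61 and -3.56, so its rank among them is not settled. The window at 2277000 on chromosome 11, in the H19 and IGF2 region ENm011, had a ratio of -2.08 ± 0.50 or lower with DNA at 4.65 ± 0.40 or more (2 probes saturated) and RNA at 2.55 ± 0.25. ENr132 had -1.95 ± 0.58 at 111635000 on chromosome 13, and ENr223 had -1.74 ± 0.39 at 73912000 on chromosome 6. RNA signal in those windows lay 1.48 ± 0.26 and 0.28 ± 0.24 above the array median.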

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

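The 31 control sequences stood apart from the random probes in data that no comparison of the report uses. No test was run here beyond the comparison of medians itself, which was chosen after the data were seen. Their Cy5 signal lay 1.11, 1.28 and 1.27 above that of the random probes on arrays 1 to 3, on the log2 scale, and it was this signal above background in unused probes that drew attention, with 1.11 the lowest array. Their Cy3 signal lay 1.00, 0.78 and 0.98 above the random probes. Control sequence 26 had the highest ratio of RNA to DNA among the 31, 2.11 ± 0.22 (SD, n = 3) relative to the array median. Control sequence 25 followed with 1.47 ± 0.31, and control sequence 15 was the lowest with -0.56 ± 0.34. The files do not say what these sequences are, and no biological explanation was tested.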

How the results depend on the processing

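Tests with the RNA channel alone, centring on the random probes, leaving out the MYC tile and the log2 threshold of 1 were chosen after the data were seen. Of 321 values under the alternatives, 300 kept their direction and their side of the threshold. Another 15 kept their direction but no longer passed, and 6 reversed. These are values of the named windows and of the named regions other than the MYC tile. All were picked as extremes, so they do not speak for all calls. With normexp and loess, 81.8% of the 4808 higher and 67.5% of the 4140 lower windows were called again. With centring on the mode these shares were 99.7% and 30.3%. The MYC tile lay between 1.69 and 2.17 and passed under every alternative run, and the share of windows at 1 or more by gene density also kept passing (11 to 37.7 points, high minus low). The cause was not tested for the changes below unless given.

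With normexp and loess, the gene density difference was 0.18 and rho 0.198, and 46.0% of called windows were higher, against 53.7% in the report. That share was 79.9% with centring on the mode, 24.3% on the random probes, 95.2% with treat, 39.7% with 5000 bp windows, 67.9% without replicate 1 and 72.5% without replicate 2. Centring on the random probes moved the median window from -0.10 to -0.26. By construction this lowers every value: 8 regions were higher and 11854 windows lower. With centring on the mode, 0 regions and 1255 windows were lower. With treat, which asks for more than 0.5, 4 regions were higher and 0 lower, and 1957 windows were higher and 99 lower. Quantile normalization gave 6420 lower windows and medians of probes 2552. Windows of 500 bp gave 7354 higher windows and 2756 at 1 or more. Windows of 5000 bp, of which fewer exist, gave 1388 higher, 2109 lower and 396 at 1 or more. The RNA channel alone gave 9225 higher, 6449 lower and 4200 at 1 or more. It also reversed ENm010 (0.23), ENr312 (0.15) and the windows at 59119000 (1.24), 2277000 (2.55), 111635000 (1.48) and 73912000 (0.28), where it leaves out the bright DNA signal. Of the 4140 lower windows, 876 were called higher with it.

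With 1 replicate left out, higher windows numbered 3742 to 4820, lower windows 1421 to 3552, windows at 1 or more 1519 to 1986, higher regions 15 to 18 and lower regions 4 to 14. No paired analysis was possible because the arrays form 1 group. Signal over background limits what can be called: 14.9% to 20.5% of tiling probes exceeded the random probes' 95th percentile in Cy5. Alternatives for genes, exons, annotation classes, gene lists, GC content and exon share were not run, since no annotation or genome of the files' build was at hand.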

Other observations

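All tests in this part were chosen after the result they bear on was seen, except that of the isolated bright windows, which was chosen before; its repeat by run was chosen after.

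In ENm007, the leukocyte receptor region, a stretch of 7 kb on chromosome 19 from 59114000 to 59120999 was bright in genomic DNA. Over its 7 windows and 181 probes, DNA signal lay at least 4.69 ± 0.35 (SD, n = 3) above the array median on the log2 scale, or at least 25.8-fold, since Cy3 was saturated on at least 1 array in 43 of the probes. RNA signal lay 1.32 ± 0.13 above the median, and the ratio was -3.34 ± 0.39 or lower.

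Among windows at a log2 ratio of 2 or more, 22 in 17 regions belonged to runs of at most 2 windows and had no window at 1 or more within 10 kb outside their own run. The brightest were the ENr322 window at 97429000 (4.62 ± 0.27), one in ENr323 on chromosome 6 at 108371000 (3.46 ± 0.43) and one in ENr231 on chromosome 1 at 148746000 (3.15 ± 0.38). In the HOXA region ENm010, the window at 27051000 on chromosome 7 stood alone at 2.32 ± 0.18.

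For the high ratio over the MYC tile, 3 technical explanations were tested. A probe design that raised the whole tile by as much as its mean would leave under 5% of its windows below 0. The share was 17.69%. All of these windows lie in the middle stretch, which was known when the bound was set. The value does not bear on a smaller or a partial effect. Sequence repeated many times would put the median Cy3 signal of its bright windows 1 or more above the array median. Dim genomic DNA would put it below. It lay 0.341 above, which argues against dim DNA as the whole cause. For repeats it does not decide, because windows picked for a high ratio over Cy3 tend to have low Cy3. Single bright windows also lay on both sides of that bound, with Cy3 at 1.54 at 128700000 and -0.11 at 128698000. A few extra copies would raise Cy3 little, since tiling probes lay close to background in Cy3, so these stay open too. Median Cy3 signal of tiling probes was 1265, 2301 and 860 on arrays 1 to 3, against 975, 1921 and 716 for random probes. Against dim DNA, the tile's mean was also 2.17 with the RNA channel alone. No biological explanation was tested, since the design has 1 group of 1 cell line.

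In the 74 windows at -1 or less, the median Cy5 signal lay 0.778 and the median Cy3 signal 2.05 above the array median. Random probes lay just 0.21, 0.18 and 0.13 below the median tiling probe in Cy5, so less RNA had no room to show and so low a ratio needs bright Cy3. These values therefore do not decide whether RNA is missing there. Gain of these stretches in Raji cells, or sequence present in many copies in any genome, stays open: Cy3 signal 10 to 30 kb away lay 0.973 above the array median, and short gains would not reach that far. Many of these windows lay close together in ENm007, so some lay 10 to 30 kb from each other. The mean DNA signal of that whole region was 1.01, 0.88 and 1.19 above the array median on arrays 1 to 3. The flank value therefore does not describe 74 separate places. No biological explanation was tested.

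Isolated bright windows may mark sequences with copies elsewhere in the genome, such as processed pseudogenes, that catch abundant RNA of another locus. Copies would raise their DNA signal, by at least 0.5 over that of bright windows in runs. The median was 1.16 in the 22 isolated windows and 0.77 in 405 windows in runs of 5 or more, a difference of 0.387 (2-sided permutation p = 0.037). Windows of a run are neighbours, so the test was repeated with 1 value per run, and 19 isolated against 71 long runs differed by 0.34 (2-sided permutation p = 0.10). The difference lay between the bounds set for either outcome, so copies elsewhere and short transcripts of the locus itself cannot be told apart.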
